A study of Homo sapiens with 16 samples.

How the data were processed

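RNA sequencing of MCF10A, a non-tumorigenic human mammary epithelial line, was used from 16 libraries. The libraries covered a Mock stock carrying the empty vector and a stock overexpressing PHF8. Each stock was sampled untreated and after 24, 48 and 72 h of TGF-β1 at 5 ng/ml, which gave 8 groups of 2 libraries. Per the labels, replicate 1 of each group was sequenced in a first round and replicate 2 in a second, so that the replicate number was also the sequencing round.

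Per the submitters' processing notes, ribosomal RNA was depleted and paired-end reads of 50 bases were aligned to hg19 with TopHat2 2.0.13. The submitters counted reads per gene with featureCounts from Subread 1.4.6 and applied DESeq2, with no version given. The deposited values are log2 expression per gene and library, on the scale of normalised read counts. Their pattern is that of a regularized log, in which the values of weakly expressed genes are shrunk towards the gene mean, but the sources do not name the authors' transformation. The base of the logarithm was settled from the values: the sum of 2 raised to each value lay between 18.8 M and 21.2 M per library. A further deposited sheet gave 2 log2 differences per gene, calculated by the authors, and a list of symbols. Its 4 columns of values under names that match no sample were not used. Read counts were not analysed here, so the true depth of each library is unknown, no counting interval is given, and fold differences of weakly expressed genes are compressed by an unknown amount.

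The table held 23368 entries, of which 28 had a symbol turned into a date and were left out, and 4064 were at 0 in every library. A gene was tested when 2 raised to its value was at least 10 in at least 2 libraries, which left 13570 genes. No pseudocount was added. The test chosen before the data were examined was edgeR, which was not run because it needs read counts. It was replaced, after the deposited values were seen, by limma 3.58.1 in R 4.3.3 on the deposited values, with a mean-variance trend. A model with 1 mean per group over all 16 libraries left 8 residual degrees of freedom, or 7 with the round as a block. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons, gene lists, naming rule and remaining alternatives were fixed before the data were examined.

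The comparisons were PHF8 against Mock at each of the 4 conditions and as the mean over them, TGF-β1 against untreated at 3 times within each stock, and a joint test of whether the response differed between stocks. Deviations of the libraries of 1 round from their group means were correlated between groups (0.207 to 0.749, median 0.461 over 28 pairs of groups), so the fit with the round as a block is given wherever it changed a call or a count by over 1.5 times. Standard errors are those of the model.

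On simulated data in which 200 of 13570 genes were changed, the mean over 4 conditions recovered 80.6% of genes at a log2 difference of 0.5, 97% at 1 and 100% at 2, with 11 false calls. PHF8 against Mock at 72 h recovered 26.9%, 76.1% and 97%, with 8 false calls. Among unchanged genes 5.18% and 5.36% had an unadjusted p under 0.05. These libraries held no shift between rounds. In a second simulation, added after the results were seen, with the estimated shift, the fit without the block recovered 52.2%, 89.6% and 97% over 4 conditions and 7.46%, 47.8% and 84.8% at 72 h, with 0 false calls in each, and 1.71% and 1.79% of unchanged genes had an unadjusted p under 0.05, fewer than expected. The fit with the block recovered 76.1%, 98.5% and 100% over 4 conditions, with 19 false calls, and 28.4%, 73.1% and 98.5% at 72 h, with 6. A further 50 draws with the shift and no difference between stocks, also added then, gave the counts expected under an unadjusted p of 0.05. In all of these simulations genes varied independently and there was no stock-by-round term. The range of the counts in the 50 draws can therefore be too narrow. Where the real difference between stocks varies between rounds, false calls over 4 conditions can be more than the simulated ones.

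The 22 gene lists held 453 symbols. All were found, 2 of them under an older symbol, and 387 were tested. They covered epithelial junctions, keratins, mesenchymal and contractile markers, transcription factors of the epithelial-mesenchymal transition (EMT), direct SMAD targets, ID genes, extracellular matrix, matrix proteases, integrins, cell cycle, histones, other histone lysine demethylases, ribosome biogenesis with MYC, interferon response, cytokines with NF-kB targets, cholesterol synthesis, hypoxia with glycolysis, keratinocyte differentiation, stress genes, and markers of luminal breast epithelium, of fibroblasts and of endothelial and blood cells. Each list was compared with all other genes by camera in limma with a preset correlation of 0.01, and again with a correlation estimated from the residuals. These residuals are of the fit without the block and include the shift between rounds. The estimated correlation can therefore be too high, and a call lost with it does not exclude a difference. Results with both the block and an estimated correlation are not reported here. Fry was run as an alternative.

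PHF8 and the EMT and TGF-β readout genes CDH1, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, ZEB2, TWIST1 and SMAD7 were named in every comparison, and a further gene of the rule is not reported here. For the mean of PHF8 against Mock and for 72 h of TGF-β1 in Mock, the 8 genes with the highest and the 8 with the lowest called differences were named, given a mean log2 value of at least 5.34 and the same direction in both rounds. For untreated PHF8 against Mock the limit was 5 each way, and for the joint test the 5 genes with the lowest p. Of each called list, up to 4 members with the lowest adjusted p were named. Genes named outside this rule are identified as such.

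Alternatives were no filter, a filter of at least 20 in at least 8 libraries, the round as a block, each round alone, the compared groups alone and each library left out in turn. Added after seeing the data were quantile normalization, median centring, limma without the trend, a stock-by-round term, a correction for GC content and transcript length, and further contrasts. Positions are not given, because the values were made on hg19 and the reference annotation used here is of another build.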

Results

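Gene expression was measured in 16 libraries of MCF10A cells, 8 from the Mock stock and 8 from the stock overexpressing PHF8, a histone demethylase of the JmjC family. TGF-β1, a cytokine that induces EMT in epithelial cells, was given for 24, 48 or 72 h or not at all, with n = 2 libraries per group. Values are log2 expression as deposited, and their sums on the linear scale were 18.8 M to 21.2 M per library. Pearson correlations across genes were 0.9822 to 0.9924 between the libraries of a group and reached 0.9969 between libraries of different groups. The first principal component, with 48% of the variance, parted untreated from treated libraries, and the second, with 19.8%, parted the sequencing rounds. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical and includes the difference between rounds.

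The first comparison asked what differed between the PHF8 and Mock stocks with and without TGF-β1, and whether EMT genes were among the differences. The labels name a single stock of each kind. The PHF8 level therefore cannot be separated from any other difference between the stocks. PHF8 itself lay between 9.26 and 9.72 in the 8 Mock libraries and between 13.64 and 14.73 in the 8 PHF8 libraries. The mean difference over the 4 conditions was 4.74 ± 0.166 on the log2 scale (SE, n = 8 per stock), or 26.8-fold, with adjusted p = 1.04e-07 in limma. It was higher in round 1 (5.20) than in round 2 (4.29). The 8 libraries of a stock come from 2 rounds, and those of 1 stock and round can vary together. The fits with and without the block do not allow for this. For genes whose difference between stocks varies between rounds, SEs and p-values of the mean over conditions can therefore be too small. Within a stock, 72 h of TGF-β1 gave a PHF8 difference of -0.23 ± 0.332 in Mock (adjusted p = 0.712) and 0.43 ± 0.332 in the PHF8 stock (adjusted p = 0.492).

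**Figure D1:**
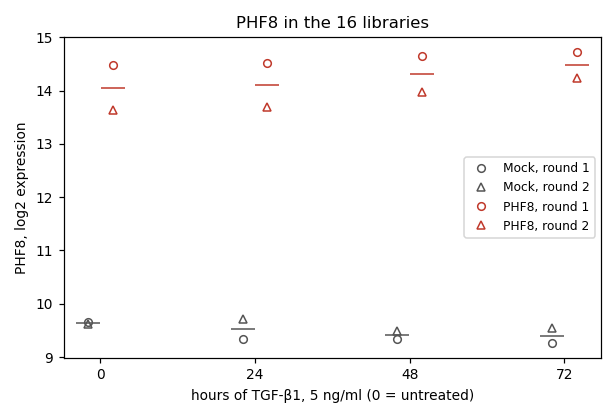
PHF8 expression (log2, vertical axis) in each of the 16 libraries by hours of TGF-β1, with circles for sequencing round 1, triangles for round 2 and a dash for the mean of 2 libraries. The 8 PHF8 libraries lie between 13.64 and 14.73 and the 8 Mock libraries between 9.26 and 9.72.

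Over the 4 conditions, C1QTNF1, SLITRK5 and BIRC3 were higher in the PHF8 stock and IL2RA, EDA and COL6A1 lower. C1QTNF1, a secreted complement-related protein, was higher by 2.01 ± 0.293 (SE, n = 8 per stock; adjusted p = 0.00944). SLITRK5, a neuronal-type membrane protein, rose by 1.42 ± 0.162 (adjusted p = 0.00268), and BIRC3, an inhibitor of apoptosis and NF-kB target, by 1.14 ± 0.11 (adjusted p = 0.00132). IL2RA, the α chain of the interleukin-2 receptor, was lower by -1.43 ± 0.139 (adjusted p = 0.00132). The ectodysplasin gene EDA (-1.02 ± 0.169, adjusted p = 0.0168) and the type VI collagen chain COL6A1 (-0.99 ± 0.126, adjusted p = 0.00522) were lower as well. Each of these genes and PHF8 had the same direction in both rounds and passed the test with any 1 of the 16 libraries left out.

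Larger or similar differences that depended on single libraries were seen in GALNTL2 (2.04, adjusted p = 0.0213), CYP1B1, a cytochrome P450 (2.01, adjusted p = 0.0212), the heparan sulfate sulfatase SULF1 (1.64, adjusted p = 0.0298), complement factor B, CFB (1.58, adjusted p = 0.041), and GGT5 (1.44, adjusted p = 0.041). Below Mock were TNNT1, a troponin of slow muscle (-1.36, adjusted p = 0.0449), FRMD3 (-1.36, adjusted p = 0.0292), the glutamate transporter SLC1A1 (-1.36, adjusted p = 0.014), ADD2, a cytoskeletal adducin (-1.10, adjusted p = 0.0159), and DISP2 (-0.98, adjusted p = 0.0196). All 10 had the same direction in both rounds. Of the 16 fits without 1 library, the call was lost in 1 for SLC1A1, 2 for ADD2, 6 for DISP2, 8 for CYP1B1 and GALNTL2, 9 for FRMD3, 10 for SULF1 and 12 for CFB, GGT5 and TNNT1. SLC1A1 lost it without the round 1 Mock library at 72 h (adjusted p = 0.0517), and ADD2 without that library (adjusted p = 0.0509) or the round 1 PHF8 library at 72 h (adjusted p = 0.0558).

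In all, 229 of 13570 genes differed, 163 higher and 66 lower in the PHF8 stock, of which 41 and 8 differed at least 2-fold. With the round as a block the count was 1237 (739 higher, 498 lower). Both counts can be too high where the difference between stocks varies between rounds, which neither fit allows for. Within round 1 alone, 3643 genes were called and within round 2 alone 805, with the times taken as replicates of a stock. These 2 fits measure no spread between rounds, so their counts can be too high as well. Leaving out any 1 of the 8 round 1 libraries gave 60 to 87 genes, and leaving out round 2 libraries gave 113 without Mock at 72 h, 144 without untreated Mock and 146 without PHF8 at 48 h.

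**Figure D2:**
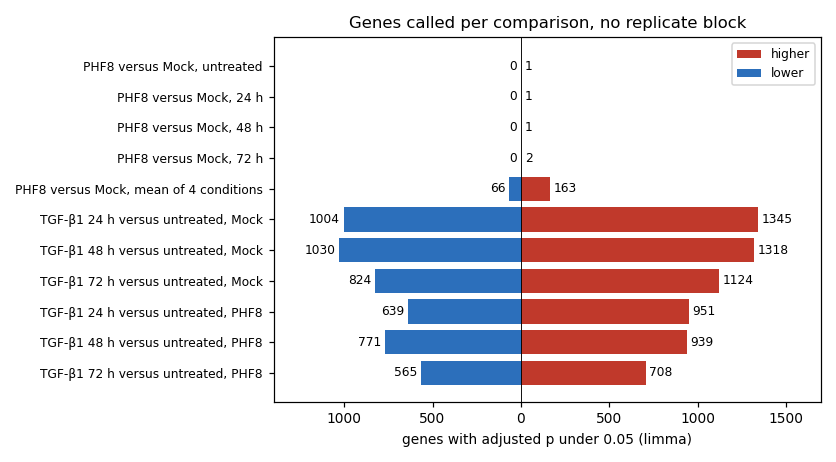
Number of genes called by limma in each comparison without a block, with genes higher in the first-named group drawn to the right and genes lower drawn to the left. PHF8 against Mock gave 1 or 2 genes at single conditions and 229 over the mean of 4, against 1273 to 2349 for TGF-β1.

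The interferon response list was higher in the PHF8 stock by camera with the preset correlation (adjusted p = 1.24e-05), but was not called with an estimated correlation (adjusted p = 0.232). Of its 28 tested members 2 rose, IFI44 by 0.49 ± 0.099 (adjusted p = 0.0365) and the RNA sensor DDX58 by 0.40 ± 0.0703 (adjusted p = 0.0207), 0 fell, and 9 rose when adjusted over the list alone. IFIT1 (0.56, adjusted p = 0.0552) and IFI35 (0.31, adjusted p = 0.0565) missed the threshold and passed with the block, at 0.0214 and 0.0163. Without single libraries IFI44 lost its call in 12 of 16 fits, and DDX58 in the 8 that left out a round 1 library.

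In the hypoxia and glycolysis list 2 of 22 members rose, the glucose transporter SLC2A3 by 0.80 ± 0.165 (adjusted p = 0.0392) and the aldolase ALDOC by 0.60 ± 0.128 (adjusted p = 0.0443), with 3 when adjusted over the list alone. The list was higher by camera (adjusted p = 0.000549), with adjusted p = 0.655 with an estimated correlation. NDRG1, a hypoxia-induced gene, was at 0.32 (adjusted p = 0.122; 0.0342 with the block) and P4HA1, a collagen prolyl hydroxylase, at 0.26 (adjusted p = 0.276). Among cytokines and NF-kB targets 2 of 20 rose, BIRC3 and the mitochondrial superoxide dismutase SOD2 (1.06 ± 0.21, adjusted p = 0.0346), and 4 rose and 1 fell when adjusted over the list alone. This list had camera adjusted p = 0.0364, adjusted p = 0.0914 with the block and adjusted p = 0.948 with an estimated correlation. IL1B, an inflammatory cytokine, was at -0.87 (adjusted p = 0.136; 0.0204 with the block), and NFKBIA, the NF-kB inhibitor, at 0.35 (adjusted p = 0.0934; 0.0348 with the block). Of the 16 fits without 1 library, SLC2A3 lost its call in 14, ALDOC in 12 and SOD2 in 10.

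Lists tied to proliferation were lower by camera with the preset correlation, with 0 members called in each, and none kept its call with an estimated correlation. Replication-dependent histones (20 tested) had a median of -0.231 and camera adjusted p = 7.44e-05, but adjusted p = 0.948 with an estimated correlation. Ribosome biogenesis with MYC (20 tested) had a median of -0.15 and adjusted p = 0.0143, and cell cycle and DNA replication (32 tested) a median of -0.154 and adjusted p = 0.0364, both with adjusted p = 0.981 with an estimated correlation. Examples were HIST1H2BK (-0.28, adjusted p = 0.277), the replication helicase subunit MCM3 (-0.32, adjusted p = 0.369) and WDR12 (-0.17, adjusted p = 0.263). CCND1, the cyclin D1 gene, was at -0.33 (adjusted p = 0.143) and passed with the block, at 0.000757. The histone median was -0.466 in round 1 and 0.00703 in round 2, and the cell cycle median -0.336 and 0.0607.

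EMT lists as a whole were not called. Mesenchymal and contractile markers had 1 member higher of 18 (camera adjusted p = 0.732), smooth muscle actin ACTA2 at 0.75 (adjusted p = 0.0209). Epithelial junctions had 1 of 30 higher (adjusted p = 0.943), the epithelial splicing factor ESRP1 at 0.99 (adjusted p = 0.022). SMAD targets had 1 of 25 lower (adjusted p = 0.973), the sphingosine kinase SPHK1 at -0.75 (adjusted p = 0.0386), and extracellular matrix had 1 higher, the type I collagen chain COL1A2 at 1.07 (adjusted p = 0.0494), and 1 lower, COL6A1, of 28 (adjusted p = 0.86). ACTA2, ESRP1, SPHK1 and COL1A2 were named after their values were seen, and of the 16 fits without 1 library ACTA2 and ESRP1 lost their call in 6 each, SPHK1 in 11 and COL1A2 in 14. EMT transcription factors had 0 of 14 called (adjusted p = 0.908). Medians changed sign between rounds 1 and 2 in epithelial junctions (-0.246 and 0.155), SMAD targets (0.0852 and -0.0874) and mesenchymal markers (-0.0426 and 0.0206).

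The remaining lists were not called either. Fibroblast markers had 1 of 6 higher, COL1A2 again (adjusted p = 0.489), and luminal breast (0 of 7, adjusted p = 0.829) and endothelial and blood markers (0 of 5, adjusted p = 0.459) had none. No member was called among keratins (0 of 13, adjusted p = 0.597), ID genes (0 of 3, adjusted p = 0.973), matrix proteases (0 of 19, adjusted p = 0.86), integrins (0 of 12, adjusted p = 0.86), other histone lysine demethylases (0 of 19, adjusted p = 0.746), cholesterol synthesis (0 of 18, adjusted p = 0.322), keratinocyte differentiation (0 of 11, adjusted p = 0.86) and stress genes (0 of 17, adjusted p = 0.86). Of these lists, medians changed sign between rounds 1 and 2 in keratins (-0.393 and 0.0913), keratinocyte differentiation (-0.268 and 0.301), endothelial and blood markers (0.589 and -0.0215), ID genes (0.048 and -0.168), integrins (0.187 and -0.0108), matrix proteases (0.0842 and -0.0375) and the demethylases (0.00937 and -0.0351).

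Of the single EMT readouts in the PHF8 stock, none passed the test over the mean of 4 conditions without the block. E-cadherin, CDH1, the main epithelial adhesion molecule, was at -0.66 ± 0.435 (adjusted p = 0.498), with -1.45 in round 1 and 0.136 in round 2. ZEB2, a repressor of CDH1, was at 0.97 ± 0.461 (adjusted p = 0.331) and passed with the block (adjusted p = 0.0195), with 1.56 in round 1 and 0.376 in round 2. The block does not allow for a difference between stocks that varies between rounds, so its p for ZEB2 can be too low. The related ZEB1 was at 0.52 ± 0.293 (adjusted p = 0.417, and 0.0523 with the block). N-cadherin, CDH2 (0.20, adjusted p = 0.592), vimentin, VIM (0.08, adjusted p = 0.792), fibronectin, FN1 (0.24, adjusted p = 0.774), SNAI1 (0.12, adjusted p = 0.907), SNAI2 (-0.16, adjusted p = 0.464), TWIST1 (0.19, adjusted p = 0.551) and SMAD7 (0.02, adjusted p = 0.962) were not called. These means join untreated and treated libraries and can hide a difference present only untreated, for which levels are given with the single conditions.

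At single conditions, PHF8 was the gene that stood out. Untreated, it was higher by 4.42 ± 0.332 (n = 2 per group, adjusted p = 0.000426) and was the only gene called in limma, with 636 genes at an unadjusted p under 0.05. Simulated libraries with the shift between rounds and no difference between stocks gave 234 on average (191 to 272 in 50 draws), so that weaker differences missed by the test are not excluded. The block added IL2RA (-1.49), C9orf64 (1.36), the glycosyltransferase LARGE (1.43) and SLC1A1 (-1.75), for 5 in all. Leaving out the filter gave 4 genes, PHF8, UGT1A7, VNN2 and LARGE. At 24 h PHF8 alone was called (4.58 ± 0.332, adjusted p = 0.000297), and 6 genes with the block, among them the acute-phase genes SAA1 (0.91) and SAA2 (1.65). At 48 h PHF8 alone was called (4.90 ± 0.332, adjusted p = 0.000143), and with the block also IL2RA (-1.40, adjusted p = 0.0481). All of these genes other than PHF8 were named after their values were seen. The EMT readouts were not called at any single condition, with or without the block. Untreated, CDH2, ZEB1, SNAI1, VIM and FN1 lay higher in the PHF8 stock than in Mock in both rounds, and CDH1 and SNAI2 lower. Each had adjusted p = 0.993 in limma. CDH2 was at 10.06 against 9.11 in round 1 and 9.28 against 8.59 in round 2. In the same order ZEB1 was at 8.73 against 7.61 and 7.07 against 6.47.

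At 72 h the actin nucleator COBL was called beside PHF8 (5.08 ± 0.332, adjusted p = 9.76e-05), at 2.21 ± 0.248 (adjusted p = 0.0135), and was named after its values were seen. The block gave 13 genes, 10 higher and 3 lower, among them BIRC3 (1.52) and the carbonic anhydrase CA2 (1.28). Leaving out the round 1 Mock library or the round 2 PHF8 library at 72 h left 1 gene. Untreated, camera called histones lower (adjusted p = 4.31e-07), interferon genes higher (0.000326), ribosome biogenesis lower (0.00214), cell cycle lower (0.00259), cytokines higher (0.00668) and mesenchymal markers higher (0.0151). No member of these 6 lists passed over all genes, 2 interferon genes rose when adjusted over the list alone, and none of the 6 held with an estimated correlation, where the lowest was adjusted p = 0.267.

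The deposited sheet of symbols held 39 genes, exactly those for which both of the authors' untreated differences were at least 1 (33 genes) or at most -1 (6 genes). It was chosen on these libraries and is not independent evidence of direction. Of 35 that were tested here, 1 was called untreated (5 with the block) and 19 over the mean of 4 conditions (26 with the block, 21 higher and 5 lower).

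The next comparison asked how Mock cells responded to TGF-β1. After 72 h periostin, POSTN, a matrix protein, rose by 6.29 ± 0.548 (SE, n = 2 per group; adjusted p = 7.95e-05), and FN1 by 5.14 ± 0.668 (adjusted p = 0.000741). LBH (5.03), KANK4 (4.93), ALOX5AP of leukotriene synthesis (4.53), the adhesion scaffold NEDD9 (4.52) and transglutaminase 2, TGM2 (4.39), were also among the largest increases that met the naming rule. FGFBP1, a carrier of fibroblast growth factors, was lower by -5.39 ± 0.58 (adjusted p = 0.00025), followed by the aldehyde dehydrogenase ALDH3A1 (-5.29), periplakin, PPL (-5.10), the alarmins S100A8 (-5.05) and S100A9 (-4.61), the epidermal transglutaminase TGM1 (-4.57), keratin 15, KRT15 (-4.33), and CYP1B1 (-4.16). Each had the same direction in both rounds and an adjusted p of at most 0.0032.

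In Mock at 72 h the EMT readouts SNAI1 (3.44 ± 0.694, adjusted p = 0.00758), SNAI2 (1.93 ± 0.198, adjusted p = 0.00018), CDH2 (1.96 ± 0.322, adjusted p = 0.00259), VIM (1.29 ± 0.232, adjusted p = 0.00417) and SMAD7, the inhibitory SMAD (2.02 ± 0.241, adjusted p = 0.000459), rose. ZEB1 was at 1.66 ± 0.586 (adjusted p = 0.085) and passed with the block, at 0.00204. CDH1 was at -1.05 ± 0.87 (adjusted p = 0.473), -1.36 in round 1 and -0.746 in round 2. It lay lower at 72 h than untreated in both rounds of both stocks. The SE is pooled over all 8 groups and holds differences between rounds that cancel from a comparison within a stock and round. The PHF8 minus Mock difference of CDH1 varied between rounds (-1.58, round 1 minus round 2). Its SE here can therefore be too large, and a fall of CDH1 is not excluded. ZEB2 (0.89, adjusted p = 0.584) and TWIST1 (-0.24, adjusted p = 0.625) were not called. SNAI1 missed the threshold without the round 2 Mock library at 72 h (adjusted p = 0.0595), and VIM without the round 2 untreated Mock library (adjusted p = 0.0503).

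**Figure D3:**
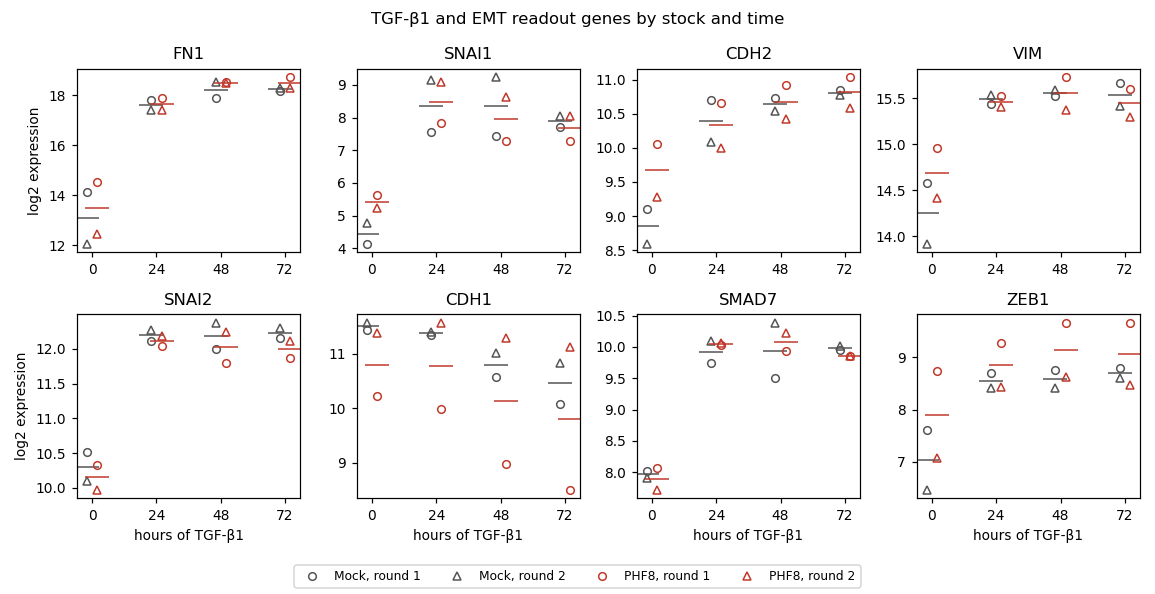
Log2 expression (vertical axes, which do not start at 0) of 8 readout genes against hours of TGF-β1, with circles for sequencing round 1, triangles for round 2, and a dash for the mean of 2 libraries. FN1, SNAI1, CDH2, VIM, SNAI2 and SMAD7 rose in Mock at 72 h, whereas CDH1 (-1.05, adjusted p = 0.473) and ZEB1 (1.66, adjusted p = 0.085) were not called.

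Extracellular matrix had the lowest camera p of the 22 lists at 72 h in Mock with the preset correlation, whereas mesenchymal markers had it with an estimated one. Of the matrix list 17 of 28 members rose and 0 fell (20 rose when adjusted over the list alone), with adjusted p = 1.21e-12, and adjusted p = 0.0479 with an estimated correlation. The basement membrane collagens COL4A1 (2.72) and COL4A2 (2.20) and the proteoglycan VCAN (1.24) were among them. Mesenchymal markers had 13 of 18 up and 0 down (14 up and 1 down over the list alone; adjusted p = 1.77e-09, and adjusted p = 0.00389 with an estimated correlation), such as cadherin 11, CDH11 (3.59), podoplanin, PDPN (2.56), and tropomyosin, TPM1 (2.37). Of direct SMAD targets 13 of 25 rose and 0 fell (19 rose over the list alone; adjusted p = 2.06e-11, but adjusted p = 0.103 with an estimated correlation), with the matrix protein TGFBI at 2.98 and LTBP2, of the latent TGF-β binding protein family, at 2.50. EMT transcription factors had 5 of 14 up (6 over the list alone; adjusted p = 0.00245, and adjusted p = 0.0858 with an estimated correlation), including SOX4 (1.81) and ETS1 (0.99).

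Further lists called at 72 h in Mock lost the call with an estimated correlation, which includes the shift between rounds. Integrins had 6 of 12 up and 2 down (7 and 2 over the list alone), with ITGB3 at 3.92 and ITGA5 at 1.87, at adjusted p = 0.00228, and adjusted p = 0.277 with an estimated correlation. Matrix proteases had 7 of 19 up and 1 down (8 and 1 over the list alone), with ADAMTS6 at 3.17 and the gelatinase MMP2 at 2.87, at adjusted p = 0.00245, and adjusted p = 0.244 with an estimated correlation. Cytokines had 7 of 20 up and 1 down (7 and 2 over the list alone), with IL11 at 3.04, CXCL3 at 2.27 and BIRC3 at -2.33, at adjusted p = 0.00245, and adjusted p = 0.335 with an estimated correlation. Fibroblast markers, of which COL1A1, COL1A2 and DCN, 3 of the 6 tested, stand also in the matrix list, had 2 of 6 up (4 over the list alone), COL1A1 at 2.72 and FAP at 2.67, at adjusted p = 0.00294, and adjusted p = 0.0811 with an estimated correlation.

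Epithelial junctions had 6 of 30 lower and 1 higher (8 and 1 over the list alone) in Mock at 72 h, at adjusted p = 0.00245, and adjusted p = 0.619 with an estimated correlation. The tight junction scaffold TJP3 (-2.93), the epithelial transcription factor EHF (-3.33) and claudin 1, CLDN1 (-2.02), fell, whereas TJP1, another tight junction scaffold, rose by 0.73. Keratinocyte differentiation had 4 of 11 lower and 1 higher (the same counts over the list alone), at adjusted p = 0.00445, and adjusted p = 0.387 with an estimated correlation. Ribosome biogenesis with MYC had 5 of 20 lower (9 over the list alone), with MYC at -1.25, nucleophosmin, NPM1, at -0.58 and fibrillarin, FBL, at -0.89, at adjusted p = 7.43e-06, and adjusted p = 0.387 with an estimated correlation. Histones had 0 of 20 called (adjusted p = 0.0035, and adjusted p = 0.619 with an estimated correlation) and cholesterol synthesis 1 of 18, IDI1 at 0.68 (adjusted p = 0.0482, and adjusted p = 0.675 with an estimated correlation). MYC missed the threshold without the round 2 library at 72 h (adjusted p = 0.0523), and CLDN1 without any 1 of the 4 compared libraries, with a lowest adjusted p of 0.0529. FBL (adjusted p = 0.108 and 0.11) and IDI1 (0.125 and 0.116) missed it without either round 2 library, and NPM1 in 3 of the 16 fits.

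The other 9 lists were not called in Mock at 72 h, although single members passed. Of 13 keratins 3 rose and 1 fell (adjusted p = 0.597), of 28 interferon genes 4 rose and 1 fell (adjusted p = 0.7), and of 22 hypoxia genes 3 rose and 1 fell (adjusted p = 0.618). Of 17 stress genes 4 rose (adjusted p = 0.297), of 7 luminal markers 1 rose and 1 fell (adjusted p = 0.227), and of 5 endothelial and blood markers 1 fell (adjusted p = 0.316). Cell cycle (0 of 32, adjusted p = 0.297), other histone lysine demethylases (0 of 19, adjusted p = 0.245) and ID genes (0 of 3, adjusted p = 0.899) had no called member.

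The change was already large at 24 h in Mock, when FN1 was up by 4.50 ± 0.668 (adjusted p = 0.00162), SNAI1 by 3.91 ± 0.694 (adjusted p = 0.004), SNAI2 by 1.89, CDH2 by 1.55 and VIM by 1.24. At that time 13 of 20 ribosome biogenesis genes were lower (adjusted p = 2.32e-09, and adjusted p = 0.21 with an estimated correlation) and 6 of 18 cholesterol synthesis genes higher (adjusted p = 0.000296, and adjusted p = 0.497 with an estimated correlation), including IDI1 (0.99) and MSMO1 (0.84). At 48 h FN1 was up by 5.12, POSTN by 5.66 and the contractile gene TAGLN by 3.09, and occludin, OCLN, was at -2.17 (adjusted p = 0.0172). The calls of OCLN at 48 h and of CDH2, VIM and MSMO1 at 24 h depended on single libraries. CDH1 was at -0.13 (adjusted p = 0.942) at 24 h and at -0.72 (adjusted p = 0.628) at 48 h.

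In Mock, 2349 genes were called at 24 h (1345 higher, 1004 lower), 2348 at 48 h (1318 higher, 1030 lower) and 1948 at 72 h (1124 higher, 824 lower), and 4865, 4741 and 4275 with the block. At 72 h 499 were at least 2-fold higher and 328 at least 2-fold lower. Without the round 2 untreated Mock library the counts were 650, 792 and 619, and without the round 1 untreated Mock library 1370 at 24 h. Without the round 2 library of the time itself they were 829, 794 and 840, and without the round 1 library at 72 h 850. Of the named genes called, 29 of 43 at 24 h, 41 of 49 at 48 h and 47 of 57 at 72 h passed in all 16 fits without 1 library.

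The same comparison in the PHF8 stock asked how that stock responded to TGF-β1. After 72 h POSTN was higher by 6.06 and FN1 by 5.02 ± 0.668 (SE, n = 2 per group; adjusted p = 0.0014). SNAI2 rose by 1.84 ± 0.198 (adjusted p = 0.000466), SMAD7 by 1.96 ± 0.241 (adjusted p = 0.000845) and CDH2 by 1.14 ± 0.322 (adjusted p = 0.0483). SNAI1 was at 2.25 ± 0.694 (adjusted p = 0.0675), VIM at 0.76 ± 0.232 (adjusted p = 0.0649) and ZEB1 at 1.17 ± 0.586 (adjusted p = 0.257), and these 3 passed with the block, at 0.00339, 0.00882 and 0.0172. CDH1 was at -0.99 ± 0.87 (adjusted p = 0.548), ZEB2 at 0.58 (adjusted p = 0.771) and TWIST1 at -0.50 (adjusted p = 0.31). CDH1 lay lower than untreated in both rounds here too, and its SE can be too large for the reason given for Mock. All of the called genes had the same direction in both rounds.

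In the PHF8 stock at 72 h, 13 of 28 matrix genes rose (18 over the list alone; camera adjusted p = 4.81e-13, and adjusted p = 0.0292 with an estimated correlation), and 10 of 18 mesenchymal markers (12 over the list alone; adjusted p = 1.73e-08, and adjusted p = 0.00581 with an estimated correlation), such as TAGLN (2.97) and the myosin light chain MYL9 (2.71). Fibroblast markers had 2 of 6 up (5 over the list alone; adjusted p = 0.00041, and adjusted p = 0.0292 with an estimated correlation). SMAD targets had 12 of 25 up (14 over the list alone; adjusted p = 7.75e-11, and adjusted p = 0.145 with an estimated correlation), with the SMAD antagonist PMEPA1 at 3.35. Epithelial junctions had 3 of 30 lower and 1 higher (4 and 1 over the list alone; adjusted p = 0.0028, and adjusted p = 0.628 with an estimated correlation), with TJP3 at -3.60 and EHF at -3.21. The differentiation genes S100A8 (-4.50), S100A9 (-4.49) and TGM1 (-3.88) fell. Of 43 named genes called, 28 passed in all 16 fits without 1 library, and CDH2 in 5 of them.

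In the PHF8 stock 1590 genes were called at 24 h (951 higher, 639 lower), 1710 at 48 h (939 higher, 771 lower) and 1273 at 72 h (708 higher, 565 lower), and 3974, 3824 and 3175 with the block. FN1 was higher by 4.15 at 24 h and by 5.01 at 48 h. Without the round 2 untreated PHF8 library the counts were 329, 567 and 393, without the round 1 library of the time itself 781, 882 and 469, and without its round 2 library 827, 653 and 552.

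Whether the TGF-β1 response differed between stocks was tested for each gene over the 3 times together. In limma 0 genes were called, with 60 at an unadjusted p under 0.05, and 0 with the block, with 158. The simulated libraries without a difference gave 189 and, with the block, 699 on average, so that the real p ran high in both fits. A difference between stocks that varies between rounds cancels from this test but stays in its residual spread, with and without the block. It therefore raises the p, and the simulations held no such term. How much of the gap it accounts for was not tested, and a count of 0 excludes little. The lowest adjusted p was 1, or 0.717 with the block. The 5 genes with the lowest p were CA2, COBL, the sulfate transporter SLC26A11, CCBE1 of lymphatic development and the channel subunit LRRC8B, each with adjusted p = 1. CA2 was at -2.43 in Mock and -0.59 in the PHF8 stock at 72 h, COBL at -3.61 and -1.64, SLC26A11 at 0.42 and -0.74, CCBE1 at 1.46 and 1.04, and LRRC8B at -2.01 and -0.98. A gene called in 1 stock and missing the threshold in the other, such as VIM or SNAI1 at 72 h, is therefore not shown to differ between them.

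Across genes, which are not independent replicates, the 72 h response of the stocks, taken from separate libraries, had a Pearson r of 0.90 and a Spearman rho of 0.821. Within round 1 r was 0.775 and rho 0.65, and within round 2 r was 0.891 and rho 0.81. Matrix genes at the upper end, such as POSTN (6.29 in Mock, 6.06 in the PHF8 stock) and FN1 (5.14 and 5.02), lay close to equal response.

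**Figure D4:**
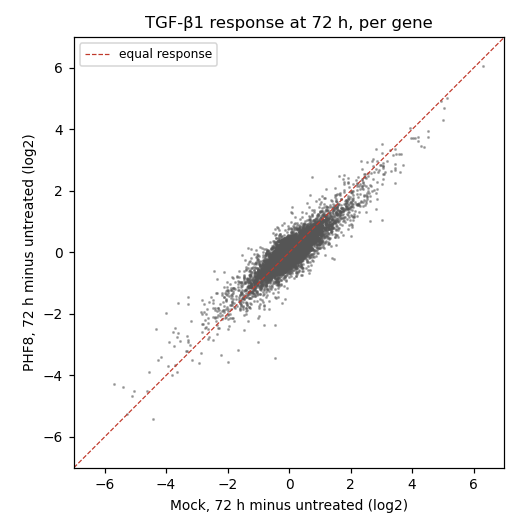
Log2 difference of 72 h TGF-β1 from untreated in Mock (horizontal axis) and in the PHF8 stock (vertical axis), with 1 point for each of the 13570 genes and a dashed line of equal response. Pearson r across genes was 0.90.

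The last comparison asked whether the PHF8 stock shifted genes in the direction of TGF-β1. The PHF8 against Mock difference at 24 and 48 h was set against the 72 h response of Mock, so that no library entered both. Across genes r was -0.141 and rho -0.0351, with r of -0.0252 and rho of 0.0896 in round 1 and r of -0.227 and rho of -0.202 in round 2. Genes called in both comparisons numbered 4, and all moved in opposite directions: BIRC3 and COBL were higher in the PHF8 stock (1.25 and 1.20) and lower after TGF-β1 (-2.33 and -3.61), and the annexin ANXA6 and the prolyl hydroxylase LEPREL2 were lower in the PHF8 stock (-0.633 and -0.787) and higher after TGF-β1 (2.09 and 0.749). COBL, ANXA6 and LEPREL2 were named after their values were seen. Of the 16 fits without 1 library, these 3 lost their call at 24 and 48 h in all 16 and BIRC3 in 11. With the block 55 genes were called in both, 11 in the same direction and 44 in opposite directions. All of these PHF8 differences came from treated cells, where a smaller TGF-β1 response in the PHF8 stock could by itself give opposite directions. Untreated, the PHF8 against Mock difference had positive slopes on the Mock response of the other round. They were 0.0549 to 0.157 over the 3 times, have no interval and were chosen after the results were seen.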

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

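The test of a stock-by-round term, the comparison of the rounds by gene and the correction for GC content and transcript length were chosen only after the data were seen. Because each group had 2 libraries, no group was large enough for a test of single outlying samples.

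The difference between stocks was not the same in both sequencing rounds: a stock-by-round term in limma called 653 of 13570 genes, with 344 higher and 309 lower in round 1 relative to round 2. Other splits, which exchange the stocks within pairs of the same time and round, do not exclude chance: 12 of 100, the real one among them, gave as many genes. The highest was 2319, several times the real count, which points to a structure of the samples. That split exchanges the stocks in 1 whole round, so that its term measures the difference between stocks itself, and the highest without it was 1518. All 11 others as large left round 1 intact: grouped after the counts were seen, the 13 others that did gave 511 to 2319 genes, and the 86 that exchanged a pair of round 1 gave 1 at most. The counts therefore followed whether the stocks of round 1 were kept, and the splits are no clean count without a change. The count of 653 ranged from 249 without the round 2 PHF8 library at 72 h to 689 without the round 1 PHF8 library at 48 h. It was 251 without the round 1 PHF8 library at 72 h, 416 and 417 without the PHF8 libraries at 24 h, 331 and 330 without those of Mock at 24 h, and 333 without either Mock library at 48 h.

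Named genes with a difference between rounds are given as round 1 minus round 2 of PHF8 minus Mock, on the log2 scale and with adjusted p under the threshold in limma. PHF8 itself had 0.906. ALDH3A1 had 2.38, CFB and SULF1 1.77 each, CYP1B1 1.69, GALNTL2 1.67, ZEB2 1.19, SOD2 1.17, BST2 1.14, BIRC3 0.581, FBLN1 0.572, IL2RA 0.527 and NFKBIA 0.47. MFAP5 had -1.79, E-cadherin, CDH1, -1.58, IVL -1.54, IL1B -1.20, TNNT1 -0.976, SPHK1 -0.712, PCNA -0.588, MCM2 -0.542, PLAUR -0.529, MCM7 -0.506, HIST1H2BK -0.459 and ETS1 -0.411. Of 30 epithelial junction genes 8 differed, all lower in round 1, where the list's median was -0.246 against 0.155 in round 2. They come from the same term as the count of 653 and carry its uncertainty.

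The spread across genes of the PHF8 against Mock difference was larger in round 1 than in round 2, with an SD of 0.36 against 0.185. A single library or time point is argued against, since the SD was larger in round 1 at 4 of 4 conditions. GC content (Spearman rho -0.0505 with the difference between rounds) and transcript length (rho 0.0681) are argued against as the whole cause, from the 95.6% of genes with a value, and removing both trends left 737 genes. A higher PHF8 level that scales up 1 shared response stays open: the rounds correlated across genes with r = 0.379, below the 0.5 set for it and above the 0.2 that would exclude it, and 429 of the 478 genes called in both rounds had the same direction, against 73.4% of those called in round 1 and 78.8% of those called in round 2. A difference in culture or library preparation between rounds also stays open, because the round equals the replicate number and the labels give neither, so that the biology of 1 culture and the batch cannot be separated.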

How the results depend on the processing

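Quantile normalization, median centring and limma without the trend were chosen after seeing the data. RLE, total-count scaling and other pseudocounts were not run, since they need read counts. Some values of PHF8 against Mock changed sign between rounds, such as CDH1 (-1.45 and 0.136), the cell cycle median (-0.336 and 0.0607) and the rho with TGF-β1 (0.0896 and -0.202). With the round as a block, the calls for PHF8 against Mock went from 1 to 5 untreated, 1 to 6 at 24 h, 1 to 2 at 48 h, 2 to 13 at 72 h and 229 to 1237 over 4 conditions. For TGF-β1 they went to 4865, 4741 and 4275 at 24, 48 and 72 h in Mock and to 3974, 3824 and 3175 in the PHF8 stock; the block removes a shift shared by the libraries of a round. Without a filter 4 genes were called untreated. From the compared groups alone, with 2 residual degrees of freedom, PHF8 against Mock gave 0 untreated, 0 at 24 h and 1 at 72 h. TGF-β1 gave 1332 at 24 h and 1104 at 48 h in Mock and 73, 356 and 230 in the PHF8 stock. Over 4 conditions, round 1 alone gave 3643 and round 2 alone 805, with the times taken as replicates of a stock. Except for the block, the filter and the fewer libraries, whose construction shows it, the cause was not tested. With each library left out in turn, and a lone library assumed to vary like the other groups, PHF8 against Mock gave 1 to 1 at each of untreated, 24 h and 48 h, 1 to 2 at 72 h and 60 to 286 over 4 conditions. The PHF8 difference was 4.64 to 4.85. TGF-β1 gave 650 to 2398, 792 to 2301 and 619 to 1957 in Mock and 329 to 1702, 567 to 1725 and 393 to 1267 in the PHF8 stock. The test between stocks gave 0 to 0, the correlation between stocks was 0.796 (without the round 2 untreated PHF8 library) to 0.90, and that of the PHF8 difference with TGF-β1 was -0.234 to -0.0303. Over all comparisons, 361 calls of named genes were lost and 53 gained with 1 library left out, against 7730 that stayed on their side. Of 22 genes named by the rule and called over 4 conditions, 7 passed in every such fit, and of 57 in Mock at 72 h, 47. The compared groups alone lost 60 and gained 5, limma without the trend lost 9 and gained 2, no filter lost 7 and gained 0, quantile normalization lost 5 and gained 1, and median centring lost 3 and gained 4. The block gained 48 and lost 0, and the stricter filter gained 2 and lost 0. The estimated correlation lost 31 list calls and fry 18. The authors' transformation and the unknown depth limit what can be said of weakly expressed genes, whose differences are compressed.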

Other observations

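The tests of 72 h against 24 h, of the size of the TGF-β1 response and of IL2RA by round were chosen only after the results were seen. The test of IL2RB was written down before its result, and the splits over 4 conditions before they were counted.

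Some genes differed between early and late TGF-β1 treatment. As no untreated libraries match these times, time in culture cannot be separated from TGF-β1 here. Over both stocks (n = 4 libraries per time), 4 genes differed in limma between 72 and 24 h, each named after its values were seen. The neutrophil chemokine CXCL3 (1.18 ± 0.122, adjusted p = 0.00605) and the hair keratin KRT34 (1.29 ± 0.168, adjusted p = 0.0388) were higher at 72 h, and C10orf116, an adipose-enriched gene (-1.92 ± 0.195, adjusted p = 0.00605), and the calcium-binding S100P (-2.30 ± 0.316, adjusted p = 0.0492) were lower. The block gave 121 genes, 36 higher and 85 lower, among them POSTN (2.28), S100A8 (-1.76) and S100A9 (-2.17). By camera the cell cycle list was higher at 72 h (median 0.445, 0 of 32 called; adjusted p = 4.49e-11, but adjusted p = 0.381 with an estimated correlation) and epithelial junctions lower (median -0.425, 0 of 30 called and 2 lower over the list alone; adjusted p = 5.67e-08, but adjusted p = 0.381 with an estimated correlation). Of the 8 splits that exchange times within pairs, 1, the real one, gave as many as 4 genes, and the highest other gave 0; 8 splits are too few for a share under 0.05. Leaving out either Mock library at 72 h left 0 genes, and the counts with other libraries left out were 1 to 6.

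For PHF8 against Mock over 4 conditions the splits cannot exclude chance. The 100 splits, drawn from 128, exchanged stocks within pairs of the same time and round. Of these 1, the real one, gave as many as 229 genes, and the highest other gave 3. With the block the real split gave 1237 and the highest other 65. The libraries of 1 stock and round can vary together, and a split that mixes their pairs breaks this up. The other split that keeps them together, which exchanges 1 whole round, gave 0 genes in both fits. As 1 such split, it is too few for a share under 0.05.

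The TGF-β1 response at 72 h was smaller on average in the PHF8 stock, although the test per gene called 0. Noise in single fold changes stays open: the amplitude ratio of PHF8 over Mock from covariances between rounds, to which independent noise adds nothing, was 0.865, but it has no interval and its bound was set after the results. The PHF8 stock may start closer to the treated state, which stays open: the untreated PHF8 against Mock difference had a slope on the Mock response of the other round of 0.0851 and 0.0641, so no library entered both. It may also end short of it, equally open, with slopes at 72 h of -0.084 and -0.0861. By their construction these slopes divide the smaller response into a part at the start and a part at the end, so they restate it and support neither explanation by themselves. These slopes replaced earlier versions that shared libraries, and a cause in the round was not tested. The slopes of the end took both signs at 24 h (0.00535 and -0.0361) and at 48 h (0.0398 and -0.0822). Those of the start were positive at 24 h (0.157 and 0.0611) and at 48 h (0.138 and 0.0549). The amplitude ratios were 0.885 at 24 h and 0.901 at 48 h. All times share the same untreated libraries, so they are not independent of each other.

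IL2RA lay between 12.7 and 14.7 in all 16 libraries and was lower in the PHF8 stock, by -1.16 in round 1 and -1.69 in round 2. A direct lowering by PHF8 stays open. Within the PHF8 stock IL2RA was higher in round 1, where PHF8 was higher too, at 4 of 4 conditions, by 0.658 untreated and by 0.748, 0.598 and 0.438 at 24, 48 and 72 h. A candidate explanation is that transcripts of the expression vector carry IL2RA, which is used as a surface selection marker in some retroviral vectors: it fell from round 1 to round 2 by more in PHF8 than in Mock at 4 of 4 conditions. This restates the difference that prompted the idea and adds no support. The labels do not name the vector, and with 2 rounds PHF8 level and round cannot be parted. Endogenous induction of the whole IL-2 receptor is argued against, since IL2RB was over the filter in 0 of 16 libraries, the bound set beforehand, and IL2RG in 0. Transcription of the cell's own IL2RA gene without the other chains was not tested and stays open.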
